A study of Mus musculus with 6 samples.

How the data were processed

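Gene expression was measured in CD71-positive erythroblasts sorted from mouse bone marrow, with 1 Affymetrix array per sample and biotin-labelled total RNA. The 6 samples fall into 3 wild type and 3 mutant RPS19 samples, as given by the genotype in the labels, and all 6 come from the FVB/N strain. The deposited values are on the log2 scale. Per the submitters' processing notes, the authors used GCOS and the RMA method in Affymetrix Expression Console. RMA corrects the background of each probe, quantile normalises across arrays and summarises the probes of a probe set. Software versions, and which arrays were normalised together, are not given in the sources used here. The table holds 22690 probe sets per array and includes 64 control probe sets. The array medians ran from 5.34 to 5.40, and no pair of arrays held identical values.

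Control probe sets were left out of the tests, which left 22626 probe sets. The platform annotation, dated 2016, gave 1 gene symbol for 20380 of these, several for 691 and none for 1555. Probe sets with several symbols or none were tested as probe sets but lent no gene a name. Entrez identifiers of 20351 probe sets matched a mouse gene table of the GRCm38.p6 assembly, which was used for symbols only and changed 0 of them. No genome build is named for the array, so no coordinates are given. For each of 12393 genes the probe set with the highest mean over the 6 arrays stood for the gene.

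Mutant and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates). P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. The same fit was made over all 22626 probe sets. Values are given as means with the SD of 3 arrays, or as log2 differences (mutant minus wild type) with the SE from the fit. Before the data were examined, 31 gene lists were fixed, covering ribosome and translation, p53, red cell, cell cycle and stress genes and markers of other marrow cells. The 30 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. After seeing the data, the estimated correlation was also run without mutant replicate 1. Camera compares a list with all other genes, whereas fry asks only whether a list's genes move. For each list the count of genes past the threshold is given over all genes tested and adjusted over the list alone. The latter adjustment does not correct across lists. Of all 12393 genes, 2158 had an unadjusted p under 0.05 by limma, so counts within a list are not read as particular to it. Single-value comparisons between the groups used an exact permutation test, two-sided, which cannot give a p below 0.1 with 3 arrays against 3.

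The rule for named genes was also fixed before the data were examined. It took Rps19, the 12 largest called rises and the 12 largest called falls without overlap between the groups, leaving out unnamed, immunoglobulin and sex-linked genes. It also took up to 4 members, by lowest p, of each list that was called or held a called gene, up to 2 of the other lists, and 21 fixed genes. Of the fixed genes, Ahsp, Bax, Rpl5 and Ddx3y were not analysed here, and 1 other is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

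The fits were tested on simulated data for this comparison, with 12393 genes and 200 of them changed. At a log2 change of 1, 78% of the changed genes were recovered with equal spread in the groups and 76% with each group's own spread. At a log2 change of 2 the share was 99% in both cases. False calls numbered 4 with equal spread and 16 with each group's own spread. Camera recovered a simulated shift of -0.5 in the proteasome list and called 0 of the other 29 lists. The simulated genes varied independently of each other, so this does not test camera where the genes of a list vary together. The simulated shift was also larger than the measured proteasome median of -0.15, so it does not test camera at a shift of that size.

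Alternatives covered the variance prior, array weights, a repeat of the quantile normalisation without controls, median centring, filters on dim probe sets, the replicate number as a block and a plain t-test per gene. They also covered a sex covariate, the choice of probe set per gene, the threshold, the gene list test and leaving out each array in turn. The sex covariate was set from the arrays themselves, by whether Eif2s3y read above Xist, which held for mutant replicate 3 alone. Scripts ran in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision of every value.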

Results

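Messenger RNA levels were measured in erythroblasts, the nucleated precursors of red cells, of 3 wild type mouse samples and 3 samples from mice carrying a transgene for mutant RPS19. The cells had been sorted from bone marrow on CD71, the transferrin receptor. The transgene encodes RPS19, a protein of the small ribosomal subunit, with the change R62W. The series title names Diamond-Blackfan anaemia, an inherited failure of red cell production in which RPS19 is often mutated. The comparison asks which transcripts differ between mutant and wild type erythroblasts. The descriptions of the 3 wild type samples share 1 tag, whereas those of the 3 mutant samples carry 3 distinct tags, of which that of mutant replicate 1 begins with another letter than the others. No label states that the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

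The wild type arrays lay close together and the mutant arrays did not. The SD of the log2 difference between 2 arrays over genes was 0.14 to 0.19 within the wild type group and 0.34 to 0.50 within the mutant group. It was 0.38 to 0.43 between the groups. The median SD of a gene was 0.088 in wild type and 0.179 in mutant samples, and the mutant SD was the larger for 77.7% of the 12393 genes. The first principal component took 38.8% of the variance and placed mutant replicates 2 and 3 apart from the other arrays, and the second took 37.7% and placed mutant replicate 1 apart. Control signals also differed between the groups. The spiked polyadenylated controls, bacterial transcripts added to the RNA before labelling, read 8.75 ± 0.016 in wild type and 12.83 ± 1.08 in mutant samples (mean log2, SD, n = 3 each, exact permutation p = 0.1). Actin control probe sets read 1.31 ± 0.054 higher at the 3' than at the 5' end in wild type and 1.70 ± 0.16 higher in mutant samples (n = 3 each, exact permutation p = 0.1). For Gapdh the same 3' minus 5' value was -0.066 ± 0.019 in wild type and 0.27 ± 0.032 in mutant samples (n = 3 each, exact permutation p = 0.1). For the transferrin receptor it was 1.72 ± 0.055 and 1.75 ± 0.13 (n = 3 each, exact permutation p = 0.8). Mutant replicate 3 read 5.78 for Xist, which is transcribed from the inactive X chromosome of females, and 8.34 for the Y-linked Eif2s3y, whereas the other 5 arrays read 11.38 to 12.07 for Xist and 2.23 to 2.45 for Eif2s3y. Of other Y-linked genes, chosen after their values were seen, Uty read 3.78 on mutant replicate 3 (2.65 to 2.79 elsewhere) and Kdm5d 2.68 (2.54 to 2.87 elsewhere).

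**Figure D1:**
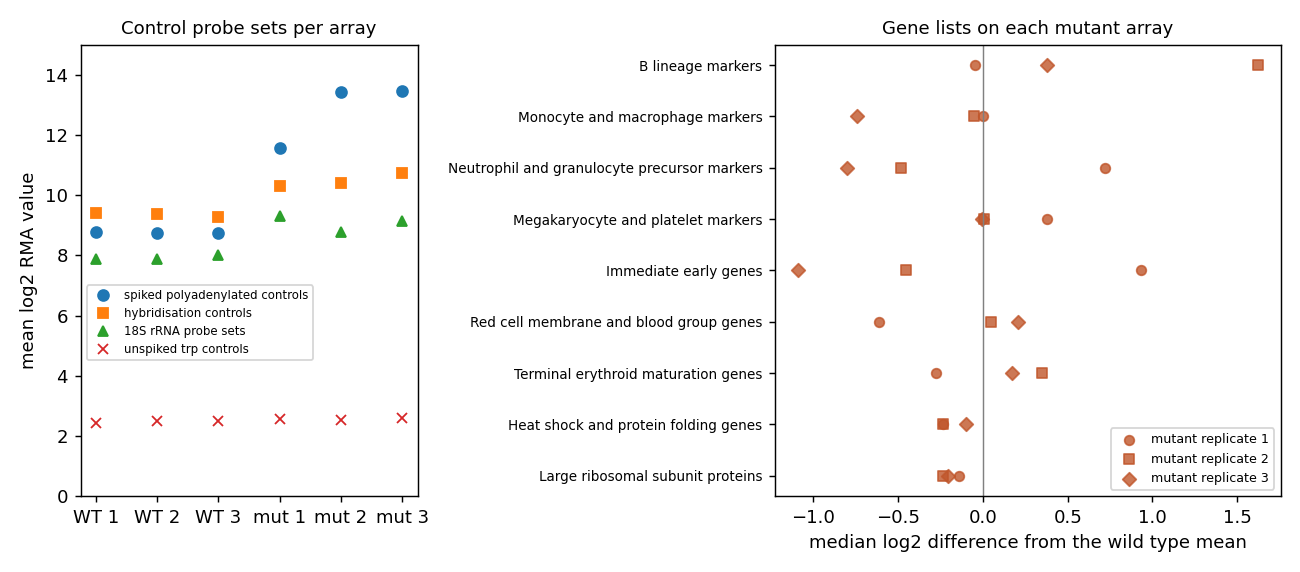
The left panel plots the mean log2 RMA value of 4 kinds of control probe set on each of the 6 arrays, and the right panel the median log2 difference of 9 gene lists on each mutant array from the wild type mean. Spiked control levels lie between 8.74 and 8.77 on the wild type arrays and between 11.58 and 13.47 on the mutant arrays, while the median over all 26 B lineage markers is -0.04, 1.62 and 0.38 on mutant arrays 1, 2 and 3.

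Rps19 was measured by 1 probe set (Entrez gene 20085) and read 12.10 ± 0.03 in wild type and 12.08 ± 0.02 in mutant samples (log2, SD, n = 3 each). The difference was -0.02 (95% confidence interval -0.22 to 0.18, adjusted p = 0.95, limma) and took the sign of 0.10 (adjusted p = 0.61) when quantile normalisation was repeated without controls. The adjusted p was 0.61 or more under all alternative settings. Whether this probe set also reads the transgene's transcript is not given in the sources used here, so its level is no check of the genotype labels.

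In the gene fit, 41 of 12393 genes changed between mutant and wild type erythroblasts, 22 higher and 19 lower in the mutant. The largest rise was that of Gdpd3, a phosphodiesterase of lysophospholipids, from 5.73 ± 0.29 to 8.44 ± 0.39 (log2, SD, n = 3 each), which is 6.52-fold (adjusted p = 0.0097). Diaph3, a formin that builds actin filaments, rose by 1.67 ± 0.13 (log2, SE) and Vwf, the von Willebrand factor of endothelial cells and megakaryocytes, by 1.48 ± 0.19. Pop4, a subunit of the RNA-cleaving enzymes RNase P and RNase MRP, rose by 1.47 ± 0.14, and Adat2, which edits transfer RNA, by 1.26 ± 0.12. Lpin1, a phosphatidate phosphatase, rose by 1.35 ± 0.16, the RNA-binding protein gene Raly by 1.31 ± 0.14 and Rpgrip1, known from photoreceptor cilia, by 1.40 ± 0.18. Rises near 2-fold were those of Fyco1, an adaptor of autophagosome transport (1.12 ± 0.10), Fam220a (1.10 ± 0.13), the DNA repair gene Ercc1 (1.09 ± 0.12) and Itfg2 (0.98 ± 0.12).

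The largest fall was that of Rap1gap, which switches off the small GTPase Rap1, from 6.52 ± 0.10 to 4.84 ± 0.12 (log2, SD, n = 3 each, adjusted p = 0.0080). Sh3d19 fell by 1.62 ± 0.12 (log2, SE) and Tmem267 fell by 1.59 ± 0.17. The splicing factor gene Cwc22 fell by 1.25 ± 0.10, Snrpd3, a core protein of the spliceosome, by 1.07 ± 0.091 and Wtap, part of the complex that methylates messenger RNA, by 0.99 ± 0.12. Ap2b1, of the clathrin adaptor, fell by 1.12 ± 0.11, the actin-binding gene Aif1l by 1.11 ± 0.15, Dcun1d1, of cullin neddylation, by 0.96 ± 0.093 and Dctn5, of dynactin, by 0.89 ± 0.095. Sdhd, a subunit of succinate dehydrogenase, fell by 0.93 ± 0.11 and the ribosomal protein gene Rpl14 by 0.90 ± 0.13. The other called genes, chosen after their values were seen, included Reep3 (0.96) and Nsmf (0.94) among rises and the immunoglobulin segment Igkv6-14 (-1.53) and Msl2 (-0.88) among falls.

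For all 41 called genes every mutant value lay on one side of every wild type value. This held for 24.7% of all genes, against 10% by chance if all arrays were independent and equally spread. The wild type descriptions share 1 tag, and the median SD of a gene was 0.088 in wild type and 0.179 in mutant samples. Separation by chance may therefore be more frequent than 10%, and no excess is read from the 24.7%. At an unadjusted p under 0.05 there were 2158 genes, and at an adjusted p under 0.10 there were 383. Over all 22626 probe sets, 528 were called, 213 higher and 315 lower, and they covered 402 genes. Of the 41 called genes 20 had several probe sets, and for 7 of these (Sh3d19, Mtdh, Rpgrip1, Snrpd3, Aif1l, Nsmf and Wtap) another probe set had the opposite sign. With the mean of all probe sets of a gene 47 genes were called, 23 of them among the 41. On that mean Rpgrip1 (0.42), Snrpd3 (-0.33), Wtap (-0.43), Aif1l (-0.37), Ap2b1 (-0.56), Dcun1d1 (-0.49), Sdhd (-0.56), Eif4e (-0.41), Fam220a (0.97) and Abhd4 (0.52) were no longer called, and Sh3d19 was called at -0.62. Leaving out wild type replicate 1, 2 or 3 left 0 called genes by limma (1415, 1255 and 1350 at an unadjusted p under 0.05), leaving out mutant replicate 1 gave 1182, leaving out mutant replicate 2 gave 30 (19 of them among the 41) and leaving out mutant replicate 3 gave 199. A test without limma's shared variance estimate also called 0 genes (1924 at an unadjusted p under 0.05), and the spiked controls differed between the same arrays by 4.07 on the log2 scale.

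**Figure D2:**
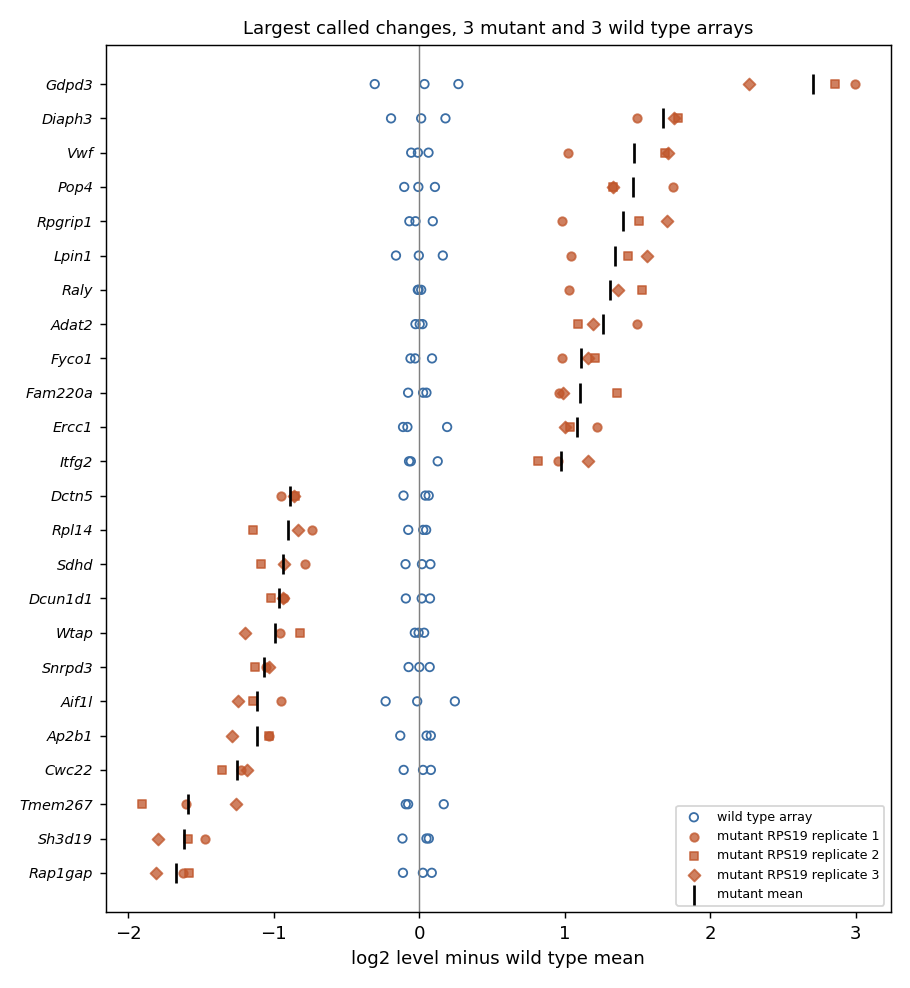
The plot shows the log2 level of the 12 largest called rises and the 12 largest called falls on each array, relative to the wild type mean, with open circles for wild type arrays, filled symbols for mutant arrays and a bar for the mutant mean. The groups do not overlap for any of these genes, from Gdpd3 at 2.71 to Rap1gap at -1.67.

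Transcripts that mark the erythroid lineage did not pass the test. Gata1, the leading erythroid transcription factor, differed by 0.12 ± 0.17 (log2, SE) and Klf1, its partner in globin gene activation, by -0.39 ± 0.22. The erythropoietin receptor gene Epor differed by -0.21 ± 0.30, the anion exchanger gene Slc4a1 by -0.03 ± 0.19 (0.09 when quantile normalisation was repeated without controls), the haem synthesis gene Alas2 by 0.35 ± 0.21 and Kit, the stem cell factor receptor of early progenitors, by -0.24 ± 0.16. The adjusted p was 0.43 or more for each of these 6 genes. Tfrc, which encodes the sort marker, read 12.14 ± 0.012 in wild type and 11.80 ± 0.31 in mutant samples (log2, SD, n = 3 each), a difference of -0.34 ± 0.15 (adjusted p = 0.31). Its dimmer probe sets, chosen after their values were seen, differed by -1.10 ± 0.097 (adjusted p = 0.0039 over probe sets) and by -0.62 ± 0.19 (adjusted p = 0.14).

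Among 38 genes of terminal erythroid maturation, 0 changed over all genes tested by limma, while adjusted over the list alone 8 rose and 3 fell. The highest were Bpgm, the enzyme that makes 2,3-bisphosphoglycerate, at 1.15 ± 0.18 (adjusted p = 0.053) and Tent5c, a poly(A) polymerase, at 1.08 ± 0.16 (adjusted p = 0.053). The 3 that fell, chosen after their values were seen, were Bsg (-0.85), Sec62 (-0.38) and Cdkn1b (-0.41). The list's median was 0.06 (camera adjusted p = 0.20). It was -0.27 on mutant array 1, 0.35 on mutant array 2 and 0.17 on mutant array 3, and 0.23 (adjusted p = 7.9e-05, or 0.66 with an estimated correlation) without mutant replicate 1. Of 33 haem and iron genes, 0 changed over all genes and adjusted over the list alone Tmem14c, a carrier for haem precursors in mitochondria, rose by 1.02 ± 0.19 and Fth1, a ferritin chain, fell by 0.63 ± 0.12 (median -0.07, adjusted p = 0.36). The haem and iron median turned to 0.02 (camera adjusted p = 0.88) without mutant replicate 1. Of 39 genes of erythroid transcription and erythropoietin signalling, 0 changed over all genes and 2 rose and 2 fell adjusted over the list alone. These were Bcl2l1, the survival factor Bcl-xL (0.78 ± 0.16), and Zbtb7a, a globin gene repressor (0.43 ± 0.089), against Nfia (-0.86) and Ikzf1 (-0.42), the latter pair chosen after their values were seen (median -0.06, adjusted p = 0.37). This list's median turned to 0.03 without mutant replicate 1, with camera's direction still down (adjusted p = 0.91).

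The 26 red cell membrane genes had a median of -0.14 (adjusted p = 0.20) and 0 of them changed, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), with Tspo2 at -1.16 ± 0.45 and Rhag at -0.51 ± 0.21. Their median was -0.61 on mutant array 1, 0.05 on array 2 and 0.21 on array 3, and 0.15 (adjusted p = 0.032, called, or 0.70 with an estimated correlation) without mutant replicate 1. Of 6 globin genes, 0 changed over all genes and adjusted over the list alone Hbb-b2, an adult beta globin, rose by 0.75 ± 0.14 (median 0.34, adjusted p = 0.28). The globin median was 0.15 (camera adjusted p = 0.88) without mutant replicate 1. Hbb-bh1, an embryonic globin, differed by 1.41 ± 0.47 (adjusted p = 0.19), with 6.61 on mutant array 1, 4.90 and 4.64 on the other mutant arrays and 3.83 to 4.06 on the wild type arrays. In 27 progenitor and stem cell genes, 0 changed over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, median -0.01, or 0.0008 when quantile normalisation was repeated without controls, adjusted p = 0.76), with Myc at -0.53 ± 0.14 (adjusted p = 0.12) and Slamf1 at 0.37 ± 0.21. The progenitor median was -0.24 without mutant replicate 1, which called the list (adjusted p = 0.0057, or 0.66 with an estimated correlation). The fixed gene Myb differed by -0.14 ± 0.12.

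Genes of protein synthesis were lower in the mutant as lists. Of the 32 small ribosomal subunit proteins in the list, 21 were measured. Of these, 17 had a lower mutant mean and the median was -0.14 (camera adjusted p = 0.0013 with the preset correlation, adjusted p = 0.96 with an estimated correlation). Over all genes 0 changed, and adjusted over the list alone Rps6 fell by 0.49 ± 0.096, while Rps26 differed by -0.32 ± 0.096, Rps29 by -0.29 ± 0.098 and Rps27l by -0.24 ± 0.085. Of the 48 large subunit proteins in the list, 24 were measured. Rpl14 fell over all genes, 6 fell and 1 rose adjusted over the list alone, and the median was -0.22 (adjusted p = 0.0031, or adjusted p = 0.96 with an estimated correlation). Rpl11, which binds the p53 regulator Mdm2, differed by -0.56 ± 0.090 (adjusted p = 0.057) and Rpl22 by -0.37 ± 0.089, and the member that rose over the list alone was Rpl27a (0.69 ± 0.10). The probe sets of Rps6, Rpl14 and Rpl27a were dimmer in wild type (8.49, 8.33 and 7.31) than those of Rpl11 (12.46) and Rps26 (13.19). Of 37 translation factors, Eif4e, the cap-binding protein, fell by 0.84 ± 0.099 over all genes (adjusted p = 0.027), and 13 fell and 1 rose adjusted over the list alone. Etf1, the release factor, differed by -0.81 ± 0.13, Eif2s2 by -0.54 ± 0.093 and Eif3a by -0.52 ± 0.087, and the member that rose, chosen after its value was seen, was Eif4g3 (0.40). This list's median was -0.14 (adjusted p = 0.0014, or adjusted p = 0.96 with an estimated correlation).

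With an estimated correlation, none of these 3 lists passed camera. On the mean of all probe sets of a gene the large subunit median was -0.13. When quantile normalisation was repeated without controls the medians of the small subunit, large subunit and translation factor lists were -0.05, -0.08 and -0.06 and their adjusted p rose to 0.51, 0.38 and 0.096, and over all alternative settings the adjusted p ran from 7.8e-05 to 0.96 for the small subunit, from 0.00029 to 0.96 for the large subunit and from 0.00021 to 0.96 for translation factors. Without mutant replicate 2 the translation factor median was -0.08 (adjusted p = 0.017), and without mutant replicate 1 it was -0.22 (adjusted p = 0.00041, or 0.66 with an estimated correlation). Of 65 ribosome biogenesis factors, 0 changed over all genes and adjusted over the list alone Nop58, of box C/D ribonucleoproteins, fell by 0.79 ± 0.13 (median -0.06, adjusted p = 0.37), with Dcaf13 at -0.35 ± 0.10. The ribosome biogenesis median was -0.088 (adjusted p = 0.023, called, or 0.92 with an estimated correlation) without mutant replicate 1. The 18S ribosomal RNA probe sets, which are control probe sets, read 1.15 higher on the mutant arrays. Hybridization controls, added after labelling, read 1.11 higher there too, so no change in 18S ribosomal RNA is read from this.

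Heat shock and proteasome genes were also lower as lists. Of 28 heat shock and folding genes, 25 had a lower mutant mean and the median was -0.13 (camera adjusted p = 0.00017 with the preset correlation, adjusted p = 0.73 with an estimated correlation). Hspa1b, an inducible Hsp70, differed by -0.83 ± 0.17 and Hspa1a, the other inducible Hsp70, by -0.81 ± 0.14 (adjusted p = 0.064), while the mitochondrial chaperonin genes Hspd1 and Hspe1 differed by -0.51 ± 0.11 and -0.47 ± 0.11. Over all genes 0 changed by limma, and adjusted over the list alone 6 fell and 0 rose. Of 37 proteasome genes, 31 had a lower mutant mean and the median was -0.15 (adjusted p = 0.00072, or adjusted p = 0.96 with an estimated correlation). Over all genes 0 changed, and adjusted over the list alone Psmb7, a catalytic subunit, fell by 0.73 ± 0.11, Psmd7 by 0.50 ± 0.11 and Pomp, an assembly factor, by 0.41 ± 0.092, while Psma7 differed by -0.45 ± 0.12. With an estimated correlation neither list passed. Without mutant replicate 2 the proteasome median was -0.09 (adjusted p = 0.017), and without mutant replicate 3 the heat shock median was -0.20 (adjusted p = 0.00036). The 26 genes of the unfolded protein response had a median of 0.0026 and a mean of -0.08 (adjusted p = 0.57), with Pdia3 at -0.60 ± 0.17 and Canx at -0.42 ± 0.11, and 0 of them changed, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05). Without mutant replicate 1 the unfolded protein response list was called, with a median of -0.15 (adjusted p = 0.00070, or 0.66 with an estimated correlation).

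Targets of p53, the tumour suppressor that ribosomal stress can activate, were tested as a list of 45 genes, and the list was not called (median 0.06, adjusted p = 0.23). Abhd4, a lipase, rose by 0.63 ± 0.086 over all genes (adjusted p = 0.044), and adjusted over the list alone Ei24 (0.52 ± 0.090) and Tap1 (0.45 ± 0.097) rose too and 0 fell. Dcxr differed by 0.58 ± 0.16. The best known targets did not pass, with the cell cycle inhibitor gene Cdkn1a at 0.06 ± 0.26, the p53 regulator gene Mdm2 at -0.08 ± 0.12 and Ccng1 at 0.05 ± 0.11 (adjusted p = 0.94, 0.78 and 0.85). Their 95% confidence intervals were -0.54 to 0.67 for Cdkn1a, -0.37 to 0.21 for Mdm2 and -0.20 to 0.30 for Ccng1. The 41 apoptosis regulators had a median of -0.0096, or 0.00058 when quantile normalisation was repeated without controls (adjusted p = 0.76), and 0 changed, over all genes or adjusted over the list alone (8 at an unadjusted p under 0.05), with Bcl2l1 at 0.78 ± 0.16 and Tradd at 0.42 ± 0.10.

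Among markers of other marrow cells, those of the B lineage were higher and those of monocytes and macrophages lower. Of 26 B lineage markers, 24 had a higher mutant mean and the median was 0.78 (camera adjusted p = 0.00053 with the preset correlation, adjusted p = 0.96 with an estimated correlation). Fcrla differed by 1.88 ± 0.45, the surface receptor gene Cd72 by 1.79 ± 0.55 and the signalling adaptor gene Blnk by 1.48 ± 0.45, while Jchain, the joining chain of plasma cells, went the other way at -2.88 ± 0.49 (adjusted p = 0.062). Over all genes 0 changed, and adjusted over the list alone Jchain fell and 0 rose. The median of the 29 monocyte and macrophage markers was -0.24 (adjusted p = 0.0031, or adjusted p = 0.96 with an estimated correlation) and 0 of them changed, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05), with Cd14 at -1.49 ± 0.60, Ms4a6c at -1.11 ± 0.42, Fcgr1 at -0.41 ± 0.11 and Mrc1 at -0.36 ± 0.11. Without mutant replicate 2 the B lineage median was 0.22 (adjusted p = 0.044) and without mutant replicate 1 it was 1.16, and without mutant replicate 3 the monocyte median was -0.01 (adjusted p = 0.80), which ended that call. Over all alternative settings the adjusted p ran from 8.6e-11 to 0.96 for the B lineage list and from 3.6e-05 to 0.96 for the monocyte list.

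Other marker lists were not called by camera. The 23 neutrophil markers had a median of -0.19 (adjusted p = 0.41) that was 0.72 on mutant array 1, -0.48 on array 2 and -0.80 on array 3, and without mutant replicate 1 the neutrophil list was called at -0.60 (adjusted p = 5.3e-09, or 0.66 with an estimated correlation). By limma 0 of them changed, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05), with Chil3 at 1.46 ± 0.56 and Cxcr2 at -0.36 ± 0.16. Of 20 megakaryocyte and platelet markers, Vwf rose over all genes and it alone rose adjusted over the list alone (median 0.01, adjusted p = 0.55), with Rab27b at 0.39 ± 0.15, F2rl2 at -0.29 ± 0.15 and Clec1b at 0.23 ± 0.13. Of 21 T and NK cell markers, 0 changed over all genes and Cd2 rose by 0.54 ± 0.11 adjusted over the list alone, with Cd3d at -0.36 ± 0.10 (median 0.04, adjusted p = 0.57). The 17 mast cell, basophil and eosinophil markers (median -0.06, or 0.00052 when quantile normalisation was repeated without controls, adjusted p = 0.95) and the 25 stromal and endothelial markers (median -0.10, adjusted p = 0.20) held 0 changed genes, over all genes or adjusted over the list alone (1 and 5 at an unadjusted p under 0.05). Their members with the lowest p were Ccr3 (-0.33 ± 0.12) and Prg3 (0.58 ± 0.30), and Col4a1 (-0.47 ± 0.12) and Pecam1 (-0.46 ± 0.13). The median of mast cell, basophil and eosinophil markers was -0.14 (adjusted p = 0.031, called, or 0.66 with an estimated correlation) without mutant replicate 1.

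The remaining lists, of metabolism, division and signalling, were not called either. Of 68 oxidative phosphorylation genes, Sdhd fell over all genes and 3 rose and 4 fell adjusted over the list alone, with Cox7c at 0.84 ± 0.13, Uqcrq at -0.54 ± 0.093 and Atp5b at -0.43 ± 0.092 (median -0.02, or 0.07 when quantile normalisation was repeated without controls, adjusted p = 0.24). Of 22 glycolysis genes, Bpgm rose and the lactate carrier gene Slc16a1 (-0.54 ± 0.13) fell adjusted over the list alone, and 0 changed over all genes (median 0.09, adjusted p = 0.57). The glycolysis median turned to -0.07 (camera adjusted p = 0.60) without mutant replicate 1. The 19 cholesterol synthesis genes had a median of 0.08 and a mean of -0.02, with camera's direction down (adjusted p = 0.76), and 0 changed over all genes. Adjusted over the list alone Fdps, which makes farnesyl diphosphate, fell by 0.66 ± 0.14, and Srebf2 differed by -0.38 ± 0.097. Of 41 interferon-stimulated genes, 0 changed over all genes, and adjusted over the list alone Ifit2 (0.65 ± 0.12) and Tap1 rose and Ifitm3 (-0.68 ± 0.10) and Igtp (-0.56) fell (median -0.10, adjusted p = 0.45). Igtp was chosen after its value was seen. The interferon median was -0.04 (camera adjusted p = 0.47) without mutant replicate 1.

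Lists of the cell cycle held 0 changed genes by limma, over all genes or adjusted over the list alone (11 for G1/S and 7 for G2/M at an unadjusted p under 0.05). The median was 0.03 in 48 G1/S genes (adjusted p = 0.76), with Rfc4 at -0.49 ± 0.13 and Ung at 0.34 ± 0.091, and 0.000785 in 56 G2/M genes (adjusted p = 0.94), with Racgap1 at 0.37 ± 0.13 and Kif2c at 0.27 ± 0.10. Both lists were called without mutant replicate 1, with a median of 0.15 for G1/S genes (adjusted p = 0.0049, or 0.66 with an estimated correlation) and 0.13 for G2/M genes (adjusted p = 0.0042, or 0.66 with an estimated correlation). The 40 genes of the amino acid and ATF4 response (median 0.02, adjusted p = 0.77) held 0 changed genes in the same counts (2 at an unadjusted p under 0.05), with Sars at -0.35 ± 0.11 and Asns at -0.46 ± 0.19. The 24 immediate early genes held 0 as well (1 at an unadjusted p under 0.05, median -0.05, adjusted p = 0.76), with Dusp2 at 0.996 ± 0.31 and Fos at -0.82 ± 0.47. Their median was 0.93 on mutant array 1, -0.45 on array 2 and -1.09 on array 3, and -0.87 (adjusted p = 8.0e-08, or 0.66 with an estimated correlation) without mutant replicate 1. The list of 4 sex-linked genes was too short to test, and its Xist level differed by -2.30 ± 1.45 (adjusted p = 0.48). Of the 30 lists tested, 7 were called by camera with the preset correlation and 0 with an estimated one (1 at an unadjusted p under 0.05) or with fry (5 at an unadjusted p under 0.05), while fry for changes in either direction called 13. Those 13 held 5 of the 7, without the B lineage (fry adjusted p = 0.20) and monocyte (0.38) lists. Lists that camera had not called were among them, such as p53 targets (0.00086), T and NK cell markers (0.0044) and stromal and endothelial markers (0.0070).

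**Figure D3:**
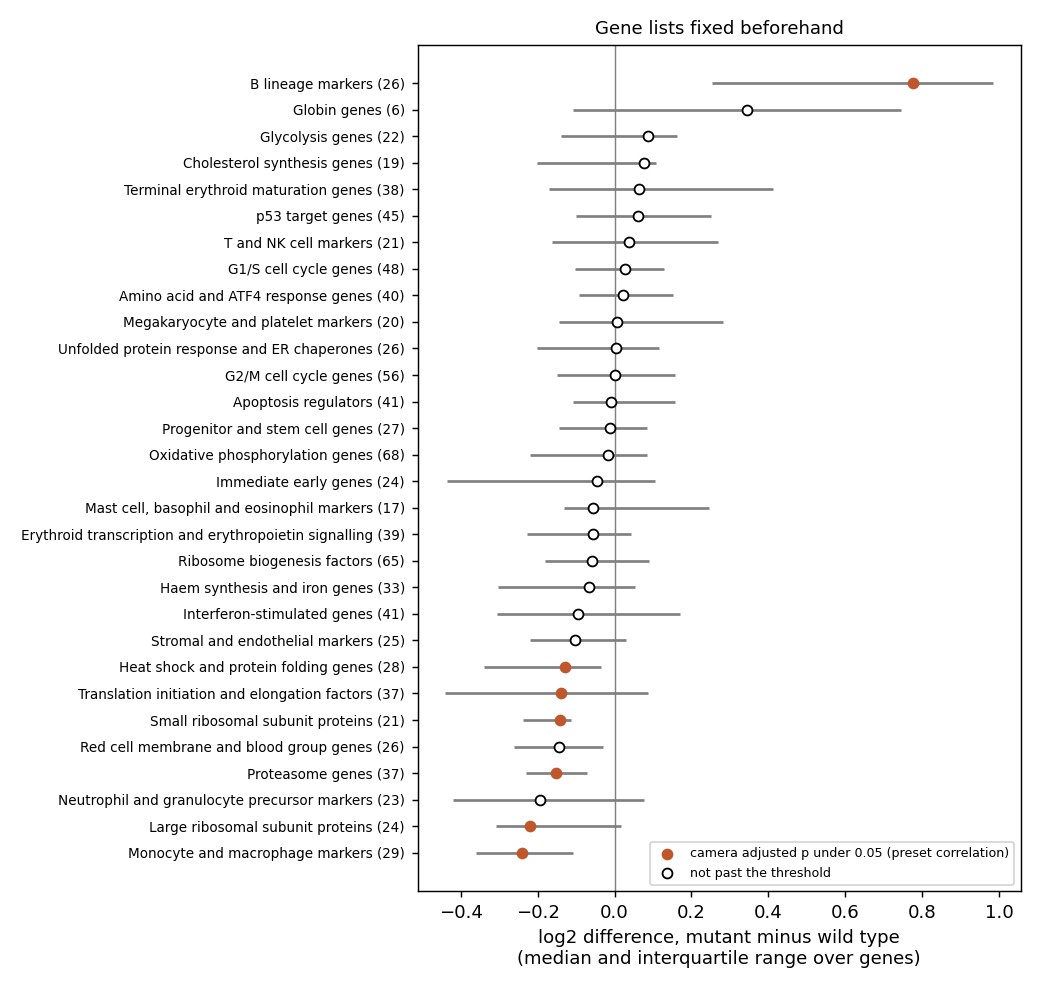
The plot shows the median (point) and interquartile range (line) of the log2 difference between mutant and wild type over the measured genes of 30 gene lists, with the number of genes in brackets and filled points for lists past the camera threshold at the preset correlation. The B lineage list stands highest at 0.78, and the 6 lower lists past the threshold have medians from -0.24 to -0.13.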

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

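The test of the spiked controls against the groups was chosen after the result was seen. Control probe sets, which the comparisons leave out, differed between the groups. The spiked polyadenylated controls were 4.07 higher on the mutant arrays on the log2 scale (8.75 in wild type, 12.83 in mutant samples, 16.8-fold), with all 3 mutant arrays above all 3 wild type arrays. The hybridization controls, added after labelling, were 1.11 higher (9.36 and 10.47) and the 18S ribosomal RNA probe sets 1.15 higher (7.92 and 9.08).

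The 41 called genes are the pattern these controls bear on. A difference in RNA input or array processing that goes with the groups may have moved some of these genes, because the spiked controls differ by 4.07 against a pooled SD of 0.76. The spiked controls read 8.74 to 8.77 on the wild type arrays, 11.58 on mutant array 1, and 13.43 and 13.47 on mutant arrays 2 and 3. Control level thus goes with the groups and also differs within the mutant group. Processing and genotype cannot be told apart here, and the mutant transgene stays open as an untested cause. Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many as 41 called genes, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.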

How the results depend on the processing

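The 41 called genes all passed again with an intensity trend (69 genes), with array weights (1292), with quantile normalisation repeated without controls (62), with a sex covariate (199) and with 1 array weight per group (111), the last chosen after seeing the data. The brighter part of the genes gave 117 and a mean log2 of at least 6 gave 110, where fewer genes were tested. Taking the most variable probe set of a gene gave 357. The mean of all probe sets of a gene gave 47, of which 23 were among the 41, and 10 of the 26 named called genes no longer passed. The thresholds of 2-fold, of an adjusted p under 0.10 and of an unadjusted p under 0.01 gave 19, 383 and 836 genes. The plain t-test gave 0 genes (1924 at an unadjusted p under 0.05) and 81 probe sets. Averaging the wild type arrays to 1 sample, chosen after seeing the data, gave 0 genes and 0 probe sets by limma (292 and 812 at an unadjusted p under 0.05), with fewer samples in the fit. Probe sets numbered 2667 with array weights and 826 with the sex covariate, which gives the values of the fit without mutant replicate 3.

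Leaving out 1 array at a time gave 0 to 1182 genes (0 without any of the wild type arrays, 1182 without mutant replicate 1, and 30 without mutant replicate 2, of which 19 were among the 41), 36 to 2544 probe sets (39, 36 and 48 without wild type replicates 1, 2 and 3, and 2544, 203 and 826 without mutant replicates 1, 2 and 3), 7 to 17 lists (17 without mutant replicate 1) and an Rps19 difference of -0.03 to -0.0018. Without mutant replicate 1, camera's direction turned and passed the threshold for 3 lists. Over the arrays left out, the median ran from -0.32 to 0.15 for red cell membrane genes, from -0.081 to 0.13 for G2/M genes and from -0.14 to 0.34 for mast cell, basophil and eosinophil markers. Rps19 took the opposite sign (0.0997) when quantile normalisation was repeated without controls. Lists called numbered 12 with array weights, 4 without controls in the normalisation, 0 with fry, 0 with an estimated correlation (0 also without mutant replicate 1, chosen after seeing the data) and 13 with fry in either direction. The replicate block gave 7 genes and 112 probe sets and the 7 lists again. Deviations of arrays with the same number correlated at 0.061, 0.022 and 0.082, and those of arrays with unlike numbers at -0.1 to 0.036. All were weak, and they do not settle whether the numbers stand for a pairing. Where no reason is given, the cause was not tested.

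All 26 named called genes kept their sign under every setting that tested them. The groups do not overlap for these genes, so settings that leave out, weight or average arrays could not turn a sign. Settings that change only the variance could not either, which leaves rescaling and the choice of probe set. Sh3d19, Rpgrip1, Snrpd3, Aif1l and Wtap each have another probe set with the opposite sign. Background signal can compress the fold of dim genes such as Rap1gap, Tmem267 and Sh3d19, whose mutant means were 4.84, 4.67 and 4.64.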

Other observations

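Mutant replicate 1 differed from the other mutant samples in genes chosen after their values were seen, and its description tag begins with another letter than theirs. The embryonic globin Hbb-y read 10.86 there, 3.16 and 3.24 on mutant arrays 2 and 3, and 6.26 to 6.42 on the wild type arrays. Hba-x, the embryonic alpha globin, read 6.37 there and 4.41 and 4.76 on the other mutant arrays. Klf1 read 10.74, against 11.34 and 11.68 on the other mutant arrays and 11.54 to 11.74 in wild type, and the blood group gene Kel read 8.90, against 10.39 and 10.40 and 10.13 to 10.26. The same array had the highest levels of the immediate early genes Egr1 (8.70, against 6.11 and 5.16) and Klf6 (8.57, against 5.57 and 4.78) and of the neutrophil gene S100a9 (12.84, against 11.18 and 10.77). Wild type arrays lay between them, at 7.69 to 7.80 for Egr1, 6.94 to 7.12 for Klf6 and 12.11 to 12.22 for S100a9. Mutant replicate 1 also differed in its spiked controls, which read 11.58, against 13.43 and 13.47 on mutant arrays 2 and 3.

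Of the tests in the paragraphs that follow, those of the erythroid share, of other marker filters, of single mutant replicates, of the actin, Gapdh and transferrin receptor controls, of the ribosomal lists alone, of the translation factor list alone and of the heat shock and proteasome lists alone were chosen after the result was seen. For the B lineage median of 0.78, more B lineage cells in the sorted fraction of all 3 mutant samples is argued against, since on mutant array 1 only 44.4% of the 18 markers (of 26) with a mean log2 over 6 lay above the wild type mean. That filter includes the mutant values, but the share was 42.3% over all 26 markers and 42.9% over the 14 with a wild type mean over 6. A lower share of erythroid cells, which would raise the markers of all other cells alike, is argued against for mutant arrays 2 and 3. There the B lineage medians were 1.62 and 0.38, and those of monocytes and macrophages -0.05 and -0.74. On mutant array 1 these medians were -0.04 and -0.0016, and that of stromal and endothelial markers was -0.12. Neutrophil markers (0.72), mast cell, basophil and eosinophil markers (1.15), megakaryocyte markers (0.38) and T and NK cell markers (0.07) were higher there. Red cell membrane genes were lower (-0.61), so a lower erythroid share stays open for mutant array 1. Over the mutant arrays the B lineage median lay 1.02 above that of monocytes and macrophages. The combined SE of 0.21 comes from resampling genes and measures no spread between samples. The monocyte and macrophage median was -0.24, or -0.01 without mutant replicate 3. For mutant replicate 2 more B lineage cells may be the source, with 94.4% of the 18 markers above the wild type mean (96.2% of the 26 and 92.9% of the 14) and its abundant transcripts among them (Ighm 11.80 against 10.10 to 10.38, Cd74 8.40 against 7.42 to 7.49). For mutant replicate 3 the source stays open, with 83.3% of the 18 markers higher (84.6% of the 26 and 78.6% of the 14, with medians of 0.68, 0.38 and 0.46) but Ighm (10.24) and Cd74 (7.49) not above the highest wild type value. Sorting on CD71 should remove most resting B cells but not dividing B precursors, which also carry CD71, and no other gate is given in the sources used here.

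The ribosome, translation factor, heat shock and proteasome lists hold 147 genes, with a pooled median of -0.15. Random lists matched on mean level shifted less, as the pooled median lay at percentile 0 of 10000 of them (5th to 95th percentiles -0.07 to -0.01, lowest -0.10). The lists were pooled because camera had called them lower in these same data, so a low rank among unselected lists was favoured beforehand. The rank therefore does not decide whether a shift that all genes of the same brightness share is the whole cause. For the 45 ribosomal proteins alone such a shared shift stays open too. They lay at percentile 1.86 among lists of their nearest genes in level, which were 0.34 dimmer. They lay at percentile 5.51 when quantile normalisation was repeated without controls. The 37 translation factors lay at percentile 0.45, and at 2.47 after that step. Rank displacement by the brighter spiked controls in the authors' quantile normalisation stays open as part of the cause. When quantile normalisation was repeated without controls, 53.6% of the pooled median remained (-0.08). That step makes the whole distribution of probe set values alike on all arrays, so the loss cannot be credited to the spiked controls alone. The heat shock and proteasome median of -0.10 then still lay at percentile 0.04 of matched lists. The step thus did not bring these genes level with matched lists, though they too were picked as called lower. Loss of 5' sequence in the mutant RNA may contribute and cannot be told apart from genotype, since the actin 3' minus 5' signal differed by 0.39 (pooled SD 0.12) between the groups and the Gapdh signal by 0.34, while that of the transferrin receptor differed by 0.03, and an effect of the transgene stays open and untested.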
